A study of Mus musculus with 20 samples.

How the data were processed

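Polyadenylated RNA was measured in 4 libraries of mouse ESCs and 16 libraries of single E4.5 mouse embryos. Per the labels' protocols, ESC libraries were made with TruSeq v2 reagents, embryo cDNA with the SMARTseq-V4 kit, and all libraries with the NEBNext Ultra II kit. The values used were estimated counts (expected counts) per Ensembl gene, which the authors deposited without library normalization and made with kallisto 0.46 on mm10, per the submitters' processing notes. How transcript estimates were brought to genes, which annotation release was used and whether feeder reads were separated is not given in the sources used here. Each table held 30265 genes, of which 29831 were matched to a symbol of the GENCODE M21 annotation (GRCm38, the same assembly as mm10) and 434 were not. 7 symbols lay on several identifiers. Positions, gene lengths and GC content came from that annotation and its transcripts.

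Estimated counts were rounded to whole numbers, which changed no library total by more than 0.000756%. Samples were grouped from the labels' titles and genotypes, with no sample left out. 2 comparisons were made, Klf5 against GFP in ESCs (2 against 2) and Klf5 siRNA against scramble siRNA in embryos (6 against 10). Genes were filtered with filterByExpr of edgeR 4.0.16 (lowest count 10), scaled with TMM and tested with robust quasi-likelihood F tests, with p adjusted by Benjamini and Hochberg and a threshold of 0.05. Tests adjusted over a list alone used the same p-values. In ESCs 2 residual degrees of freedom remained, and the common biological coefficient of variation was 0.163, against 0.739 in embryos. Folds are fitted values. CPM use the scaled library sizes, except floors and Y-linked totals, which use total counts, and log2 CPM a prior count of 2. A fold against a group whose libraries are all at 0 was computed against a floor of 3 counts per library. Library measures in embryos were compared by exact permutation of the embryo labels. Floors cover counting error only, since amplified reads are not independent molecules.

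22 gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01), adjusted over the lists of a comparison. The 7 main lists held trophectoderm, inner cell mass and naive pluripotency, primitive endoderm, 2-cell-like, formative, FGF/ERK and Krüppel-like genes. The others held epithelial junction, YAP/TEAD, WNT, mesendoderm, neuroectoderm, fibroblast, p53, integrated stress, interferon, imprinted, germline, maternal oocyte, Xist and Y-linked, glycolysis and hypoxia, and lipid and cholesterol genes. A list level is the mean log2 CPM of a list's measured genes relative to the control mean. The lists, the tests and the rule for naming genes were set before the data were examined. The rule named Klf5, the 8 rising and 8 falling genes with the smallest p and an absolute log2 fold change of at least 1, up to 4 members past the threshold in a main list and 2 in another list, or the member with the smallest p where none passed, and up to 6 genes called in both comparisons in opposite directions and 6 in the same direction. Predicted genes were left out of the rising and falling genes, and where fewer than 5 qualified 5 were taken. Other list members are given as values beside their lists. Not every gene that the rule named is reported here.

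Alternatives set before the data were examined were RLE and upper quartile scaling in edgeR, DESeq2 1.42.0 with its own filter, limma voom, no filter, a filter at 5 CPM, a test against a 1.5-fold change, each library left out in turn, the replicate numbers as a block (in embryos only the 12 whose numbers both groups share, without scramble embryos 7 to 10), and for lists camera with an estimated correlation and fry. For embryos they also included leaving out embryos with few detected genes, total counts or detected genes as a covariate, and voom with sample quality weights. Alternatives chosen after the data were seen were an offset for each library's trend with gene length (lowess span 0.3), leaving out Klf5 siRNA embryos 2 and 4 or scramble embryos 5 and 6, the mitochondrial percent as a covariate, a crossed pairing of ESC replicates, the Krüppel-like list without Klf5, DESeq2 on the genes that filterByExpr keeps, the 12 embryos of the replicate block without the block, and leaving out libraries in the comparison of both experiments. Families of genes sharing a symbol root, with at least 8 measured members, were also tested with camera. Outlying values were sought with Dixon's test in 190 groups of values. 100 splits of the 16 embryos, the real one included, and 10000 bootstrap draws over genes (95% intervals, which cover the spread between the genes of a list) were used in the closing tests.

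The fits were tested on simulated data with 200 changed genes. At ESC depth and spread edgeR recovered 18.5%, 60.0% and 81.2% of genes changed by 1.5-fold, 2-fold and 4-fold among 15716 genes, and 28 of its 131 calls were false. At embryo depth and spread it recovered 0%, 3.03% and 57.8% among 11932 genes, and 5 of 44 calls were false. Work used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.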

Results

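RNA sequencing was read from 20 mouse samples in 2 experiments on Klf5, a Krüppel-like zinc-finger transcription factor. The first experiment used embryonic stem cells (ESCs, pluripotent cells derived from the blastocyst) of a C57BL/6J line kept with LIF on irradiated fibroblast feeders. 2 libraries came from cells overexpressing Klf5 and 2 from cells overexpressing green fluorescent protein (GFP). The second experiment used single embryos at E4.5, the late blastocyst stage, cultured in KSOM medium after injection of small interfering RNA (siRNA). 10 embryos had received a scramble siRNA and 6 an siRNA against Klf5, with 1 library per embryo. The labels do not say that the ESC replicates were separate cultures, so p-values in that experiment measure only the spread between these samples, which may be technical. The ESC experiment asks which transcripts change when Klf5 is raised, and the embryo experiment which change when it is lowered.

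In units of 1e6 counts, the ESC libraries held 26.8 and 36.9 for GFP 1 and 2, and 34.6 and 37.5 for Klf5 1 and 2. The embryo libraries were shallower. Scramble embryos 1 to 10 held 17.1, 14.7, 16.4, 15.0, 24.9, 24.9, 15.0, 19.1, 22.7 and 21.2, and Klf5 siRNA embryos 1 to 6 held 14.9, 17.3, 23.4, 20.8, 17.6 and 21.2. A count of 3, the most that a count of 0 allows, corresponded to 0.0800 to 0.112 CPM (counts per 1e6 counts) in ESC libraries and 0.120 to 0.204 CPM in embryo libraries, for counting error only. Between 19381 and 19871 genes had a count in ESC libraries and between 13114 and 15568 in embryo libraries. No 2 libraries of a group were counted as repeats of 1 library, since their counts differed by more than counting noise (lowest chi-square per degree of freedom 22.6 between ESC replicates and 77.0 between embryos). This comparison serves only to find repeated libraries and is no measure of replicate quality.

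Klf5 transcript, the target (ENSMUSG00000005148, chromosome 14, 99298691 to 99315036, mm10), stood at 912 ± 42.7 CPM (SD, n = 2) in Klf5-overexpressing ESCs and at 75.6 ± 6.83 CPM (n = 2) in GFP cells. The libraries held 942 and 882 CPM against 80.5 and 70.8 CPM, a 12.1-fold difference (log2 fold change 3.59 ± 0.14 SE, edgeR quasi-likelihood adjusted p = 0.000323). Primitive endoderm genes were the list farthest from 0 on the median. Sox7 rose 10.3-fold, from 0.931 ± 0.0900 to 9.60 ± 4.80 CPM, and Hnf4a 9.19-fold, both encoding endodermal transcription factors. Cubn rose 7.70-fold and Dab2 4.95-fold, encoding an endocytic receptor and an endocytic adaptor of extraembryonic endoderm. Cldn4, encoding a tight-junction claudin, fell 2.81-fold from 837 ± 149 to 298 ± 47.6 CPM.

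Of 24 primitive endoderm genes measured, 4 rose and none fell over all genes tested, and 9 rose adjusted over the list alone. The median log2 fold change was 1.40 (limma camera adjusted p = 1.6e-10), and adjusted p = 0.592 with an estimated correlation. The list level was 0.77 in Klf5 1 and 1.91 in Klf5 2 relative to the GFP mean, so that the median was 0.77 without Klf5 2, with Sox7 at a log2 fold change of 2.74 rather than 3.37 and Cubn at 2.27 rather than 2.95. Gata6 (5.01-fold, adjusted p = 0.0632), Sox17 (4.56-fold, adjusted p = 0.0844) and Gata4 (3.31-fold, adjusted p = 0.158) missed the threshold. Fibroblast markers, which feeder cells express, moved with the group. Of 18 measured 1 rose, Col1a2 at 1.72-fold (6 rose adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.00117), and adjusted p = 0.516 with an estimated correlation.

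**Figure D1:**
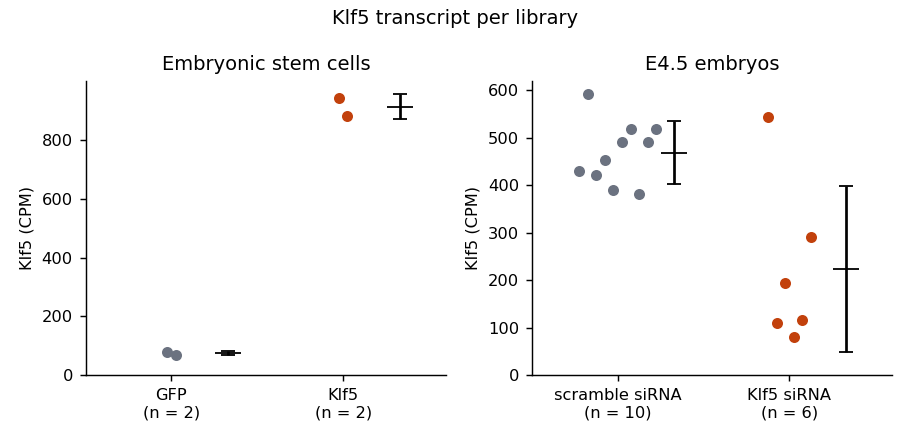
Klf5 transcript in CPM in each library, with ESCs on the left and single E4.5 embryos on the right; dots are libraries, horizontal ticks group means and bars 1 SD. Klf5-overexpressing libraries lay at 882 and 942 CPM against 70.8 and 80.5 CPM in GFP libraries, and 5 of 6 Klf5 siRNA embryos lay below the 10 scramble embryos, while embryo 1 lay at 543 CPM.

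Inner cell mass and naive pluripotency genes moved both ways in ESCs. 5 of 28 rose and 1 fell (13 and 2 adjusted over the list alone). Jam2, an adhesion molecule gene, rose 2.94-fold, Tbx3, a T-box factor gene, 2.14-fold, and Tdh, encoding threonine dehydrogenase, 1.95-fold, while Dppa3, encoding a maternal-effect chromatin factor, fell 4.02-fold. The median was 0.46 (camera adjusted p = 2.2e-05), and adjusted p = 0.592 with an estimated correlation. It was 0.21 without Klf5 1. Pou5f1 lay at 1.13-fold (adjusted p = 0.486) and Nanog at 1.96-fold (adjusted p = 0.125).

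Trophectoderm genes had a median of −0.41 in ESCs, with 0 of 33 rising and Cldn4 alone falling (3 rose and 12 fell adjusted over the list alone; camera adjusted p = 9.1e-05). The adjusted p = 0.592 with an estimated correlation, and the median was −0.23 without GFP 1. Cdx2 stood at 1.19 ± 0.342 CPM in GFP cells and 1.21 ± 0.400 CPM with Klf5 (adjusted p = 0.969). Of 28 epithelial adhesion and junction genes, none rose and 5 fell (2 and 9 adjusted over the list alone), among them Esrp1, an epithelial splicing factor gene, at 2.38-fold. Their median was −0.28 (camera adjusted p = 2.2e-05), and adjusted p = 0.622 with an estimated correlation. This median was −0.14 without GFP 1, −0.55 without GFP 2, −0.17 without Klf5 1 and −0.54 without Klf5 2. 2 of 16 p53 target genes fell, Plk2 at 2.02-fold and Trp53inp1 at 1.66-fold (6 adjusted over the list alone). The list median was −0.35 (camera adjusted p = 8.3e-05), and adjusted p = 0.592 with an estimated correlation. It was −0.21 without Klf5 1.

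Among genes of the 2-cell-like state, 2 of 19 measured rose and none fell (6 adjusted over the list alone). Zscan4b was at 0 in both GFP libraries and at least 12.2-fold higher with Klf5 (3 counts per library as the floor), although its reads cannot be separated with certainty from near-identical family members. Sp110 rose 4.40-fold. The list median was 0.93 (camera adjusted p = 0.00120), and adjusted p = 0.592 with an estimated correlation. It was 0.54 without GFP 1 and 1.55 without GFP 2. In the Krüppel-like factor family Klf5, Klf3 (2.39-fold) and Klf9 (1.55-fold) rose among 17 members (6 rose and 1 fell adjusted over the list alone). The median of −0.02 and the mean of 0.28 differed in sign (camera adjusted p = 0.000255, direction up), and adjusted p = 0.516 with an estimated correlation. The result rested on Klf5, which the experiment itself raised. Without Klf5, left out after the data were seen, the other 16 members had a median of −0.05 and a mean of 0.07 and did not pass (adjusted p = 0.25). With Klf5 included the median was 0.23 without GFP 2 and 0.16 without Klf5 2, and the call was lost with limma voom (adjusted p = 0.144) and with a length offset (adjusted p = 0.274).

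3 further lists passed camera in ESCs. In the WNT target list Cdx1, a caudal-type homeobox gene, rose 3.57-fold among 14 members, with a median of 0.43 (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00515, and adjusted p = 0.516 with an estimated correlation). Imprinted genes had a median of −0.25, with Slc38a4 the 1 of 16 that fell, at 1.82-fold (2 adjusted over the list alone; camera adjusted p = 0.00515, and adjusted p = 0.516 with an estimated correlation). The imprinted median was −0.17 without GFP 1, −0.48 without GFP 2 and −0.52 without Klf5 2. Interferon-stimulated genes had a median of −0.49 with 0 of 17 past the threshold, adjusted over the list alone or over all genes (camera adjusted p = 0.00973, and adjusted p = 0.516 with an estimated correlation). Irf7 had the smallest p among them at a log2 fold change of −0.94 (adjusted p = 0.0663, and 0.0352 without Klf5 2).

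The other 11 lists did not pass in ESCs. Formative genes had 3 rising (Foxd3, 2.59-fold; Sox3, 2.23-fold; Tcf15, 1.99-fold) and Grhl2 falling 3.11-fold among 16 (3 and 2 adjusted over the list alone; median 0.31, camera adjusted p = 0.25, and a median of 0.08 without Klf5 1). FGF/ERK feedback genes had 3 rising, Spry2 at 2.24-fold, Etv5 at 1.87-fold and Spred2 at 1.83-fold, and 2 falling, with Fosb at 2.13-fold, among 18 (5 and 2 adjusted over the list alone; median 0.09, adjusted p = 0.495). 1 member rose and none fell in the lists of YAP/TEAD targets (Arhgef17, 1.49-fold, median −0.06, adjusted p = 0.576), neuroectoderm (Sox1, 5.39-fold, median 0.09, adjusted p = 0.590) and integrated stress (Xbp1, 2.07-fold, median −0.16, adjusted p = 0.523), each also 1 adjusted over the list alone. The same held for germline genes (Stra8, 2.30-fold, median −0.05 against a mean of 0.20 and a camera direction up, adjusted p = 0.431, 2 rising adjusted over the list alone). In the maternal oocyte list Ooep rose 1.54-fold against a list median of −0.43 (adjusted p = 0.408; 1 rose and 3 fell adjusted over the list alone). Hk2, encoding hexokinase, rose 1.79-fold and Egln3 1.58-fold in the glycolysis and hypoxia list (2 adjusted over the list alone; median −0.02 against a camera direction up, adjusted p = 0.802). No member passed among mesendoderm genes (1 adjusted over the list alone; Gsc, log2 fold change 1.09, adjusted p = 0.0561; list median 0.24, adjusted p = 0.241) or lipid and cholesterol synthesis genes (0 adjusted over the list alone; Fasn, 0.68, adjusted p = 0.0962; list median 0.02, adjusted p = 0.673). The same was true of the Xist and Y-linked list, of which Xist was not measured. Adjusted over the list alone 1 member fell. Kdm5d stood at −1.31 (edgeR adjusted p = 0.0919), and the list median was −0.30 (camera adjusted p = 0.408). Leaving out a library brought 3 of these lists past camera, germline without GFP 2 (median 0.29, adjusted p = 0.00460), integrated stress without Klf5 2 (−0.50, 0.00148) and Xist and Y-linked genes without Klf5 1 (−5.13, 0.0227). The medians of all 11 lists moved by more than 1.5 times or changed sign with 1 library left out. Those of the formative, YAP/TEAD, mesendoderm, neuroectoderm and maternal oocyte lists kept their sign. No direction is read from any of the 11, since none passed camera with all libraries. Sox1 lay at 3.11 rather than 2.43 on the log2 scale without GFP 2, and Gsc passed without Klf5 2 (adjusted p = 0.0411).

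The genes with the smallest p in ESCs were, besides Klf5 and Cdx1, Islr2 (3.55-fold higher), Fgfr3, a fibroblast growth factor receptor gene (2.92-fold), Zfhx2 (2.74-fold), Ckap4 (2.09-fold), Nynrin (2.47-fold) and Fgf10, a growth factor gene (6.90-fold). Falling genes were led by Leng8 (2.44-fold lower), Dll1, a Notch ligand gene (2.15-fold), Igsf9 (2.37-fold), Snhg11 (2.16-fold) and Klhl13 (4.32-fold). Nutf2-ps1, a locus named as a pseudogene whose reads can be shared with its parent gene, was lower and is uncertain in size too (log2 fold change −7.14, −10.15 without Klf5 1 and −6.20 without Klf5 2). Of 15968 genes tested, 444 passed an adjusted p of 0.05, 266 higher and 178 lower, and 3710 had an unadjusted p below 0.05. With 2 libraries per group the calls were fragile. 1 gene, Klf5, passed without GFP 1, 169 without GFP 2, 505 without Klf5 1 and 998 without Klf5 2, and 1 gene passed a test against a 1.5-fold change. All 55 named genes called here other than Klf5 lost their call in that test and without GFP 1.

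**Figure D2:**
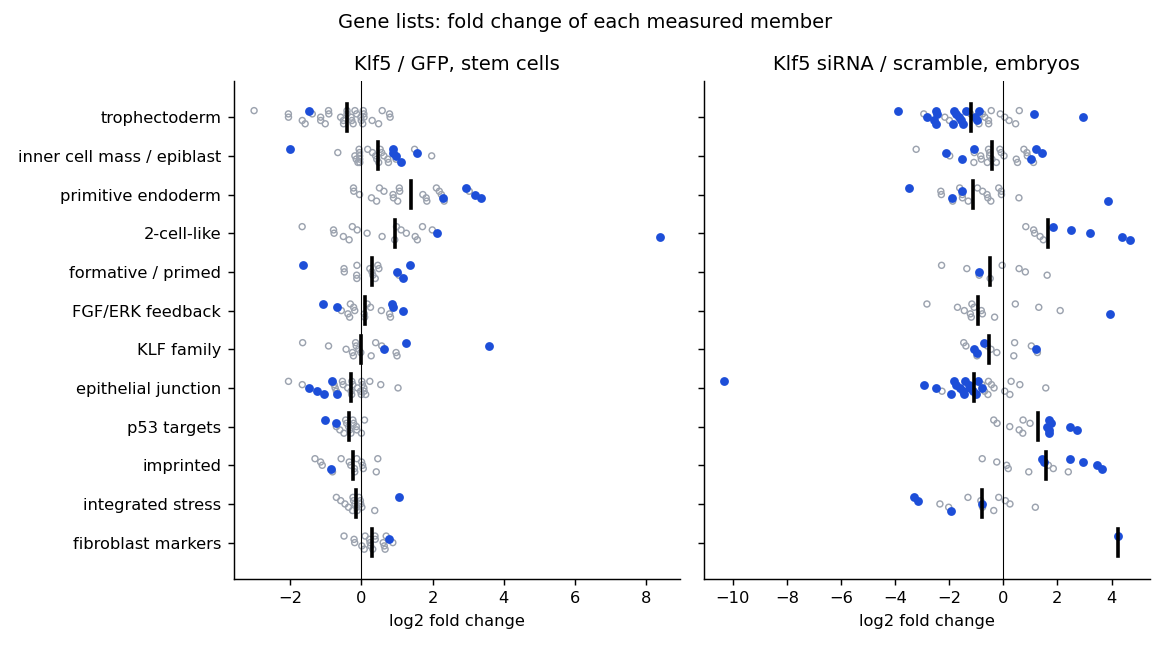
Fitted log2 fold change of each measured member of 12 gene lists, for Klf5 against GFP in ESCs (left) and Klf5 siRNA against scramble siRNA in embryos (right). Filled dots are genes past an adjusted p of 0.05 over all genes, open dots the others, and vertical ticks list medians, which in embryos were −1.20 for trophectoderm and 1.30 for p53 targets; fitted values of genes at 0 in 1 group, such as Zscan4b in ESCs, give no size.

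In embryos Klf5 transcript averaged 223 ± 174 CPM (n = 6) after Klf5 siRNA and 469 ± 65.7 CPM (n = 10) after scramble siRNA (log2 fold change −1.07 ± 0.33 SE, edgeR adjusted p = 0.0273). By an exact two-sided permutation test of mean log2 CPM over all 8008 arrangements the difference was −1.38 (p = 0.00137, adjusted over 6 library measures 0.00412). The Klf5 siRNA embryos 1 to 6 held 543, 111, 195, 80.8, 117 and 292 CPM, and the scramble embryos between 382 and 592 CPM. The embryo labelled Klf5 siRNA 1 was thus at the level of the controls and its target level goes against its label, with no lowering of the transcript left at E4.5. It was kept, and directions drawn from the group include it. Without it the log2 fold change of Klf5 was −1.56 (adjusted p = 0.00130). The call was lost without Klf5 siRNA 2 (−0.93, adjusted p = 0.0619), 3 (−1.06, 0.0509), 4 (−0.91, 0.0583) or 5 (−0.95, 0.0672).

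Library make-up also differed between the siRNA groups. All scramble libraries carry lower library numbers than the Klf5 siRNA libraries, so siRNA and library order cannot be told apart. Mitochondrial transcripts took 5.02 ± 2.78% of counts in Klf5 siRNA embryos and 12.1 ± 4.84% in scramble embryos (exact permutation p = 0.00724, adjusted 0.0145; below the control mean in 6 of 6). Ribosomal protein transcripts took 10.9 ± 2.35% and 6.98 ± 1.70% (exact permutation p = 0.00125, adjusted 0.00412) and lay above the control mean in 6 of 6. The highest ribosomal share, 14.2%, was that of the embryo labelled Klf5 siRNA 1. Total counts (exact permutation p = 0.964) and genes with a count (14286 ± 613 against 14640 ± 551, exact permutation p = 0.258) did not pass, nor did the share of the 10 most abundant genes (12.6% against 17.5%, exact permutation p = 0.0516, adjusted 0.0774). Fold changes also followed transcript length across 12292 genes (Spearman −0.293 across genes, which are not independent replicates), with a median log2 fold change of 0.88 in the shortest decile and −0.34 in the longest. These shifts accompany every gene group described here for embryos.

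Trophectoderm genes were lower in Klf5 siRNA embryos. Of 33 measured, 16 fell and 2 rose (18 and 2 adjusted over the list alone). Elf5 (ENSMUSG00000027186, chromosome 2, 103411688 to 103450989), a trophoblast ETS factor gene, fell 14.9-fold from 21.4 ± 15.1 to 1.44 ± 1.37 CPM, and Cdx2, a trophectoderm homeobox gene, 5.41-fold. Lcp1, an actin-bundling protein gene, fell 5.91-fold, Eomes, a T-box factor gene, 3.09-fold, and Fgfr2, a fibroblast growth factor receptor gene, 2.97-fold. The 2 that rose were Ascl2, an imprinted trophoblast factor gene, at 7.64-fold, and Slc2a1, a glucose transporter gene shared with the glycolysis list. The list median was −1.20 (camera adjusted p = 5.5e-07), and adjusted p = 0.196 with an estimated correlation. All 6 Klf5 siRNA embryos had a list level below those of all 10 controls (−2.58 to −0.53 against −0.39 to 0.39). Chance gives such an ordering with a share of 0.0250%. The embryo labelled Klf5 siRNA 1, whose Klf5 transcript was at the control level, lay at −0.60. The lower list level was thus also present where Klf5 transcript was not lowered at E4.5. Without the embryo labelled Klf5 siRNA 1 the list still passed (camera adjusted p = 5.8e-08). Without embryos 2 and 4, left out after the data were seen because they lay farthest out on the first principal component, 8 genes fell and none rose. A replicate block can use only the 12 embryos whose numbers both groups share, without scramble embryos 7 to 10. In these 12 embryos 10 members fell without the block and 9 with it. Elf5 lay at a log2 fold change of −4.59 without Klf5 siRNA 6. The call of Cdx2 was lost without embryos 2 and 4 (adjusted p = 0.0503) or scramble embryos 5 and 6 (0.0515), that of Eomes with the mitochondrial percent as a covariate (0.0630) and that of Ascl2 without embryos 2 and 4 (0.0766).

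Epithelial adhesion and junction genes, 28 measured and 5 of them shared with the trophectoderm list, had 16 members lower and none higher (16 adjusted over the list alone). Cdh1 (ENSMUSG00000000303, chromosome 8, 106603351 to 106670246), encoding E-cadherin, fell 3.86-fold from 492 ± 239 to 128 ± 47.9 CPM, and Dsp, encoding desmoplakin, 5.62-fold. The median was −1.08 (camera adjusted p = 7.6e-06), and adjusted p = 0.0751 with an estimated correlation. The level was below all controls in 6 of 6 embryos, the embryo labelled Klf5 siRNA 1 among them, and 8 genes fell without embryos 2 and 4. In the 12 embryos of the replicate block 10 fell without the block and 6 with it.

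**Figure D3:**
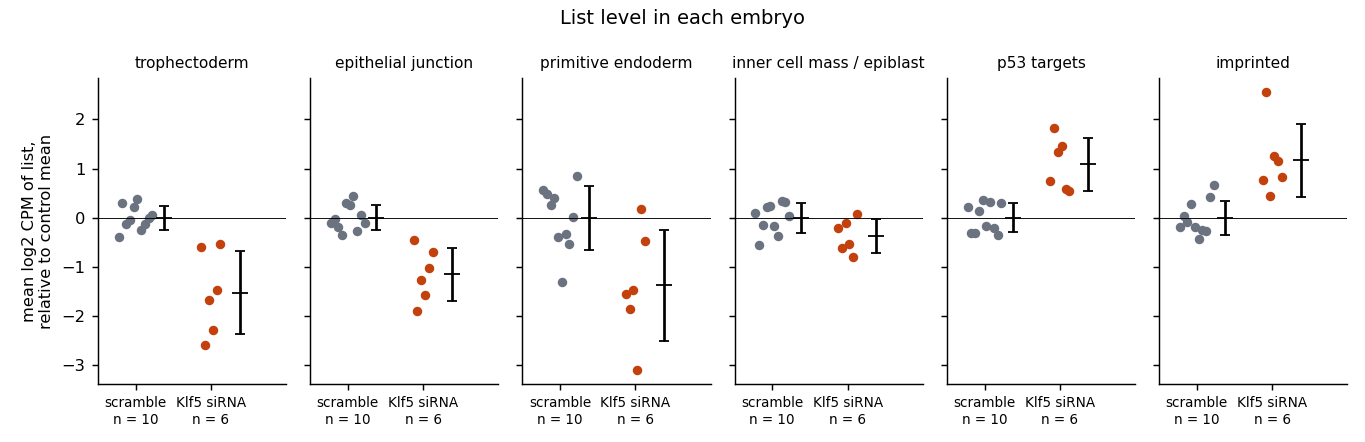
Mean log2 CPM of 6 gene lists in each embryo relative to the scramble mean; dots are embryos, ticks group means and bars 1 SD, with 10 scramble and 6 Klf5 siRNA embryos. All 6 Klf5 siRNA embryos lay below all controls for trophectoderm and epithelial junction genes and above all controls for p53 targets.

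Target genes of p53 were higher. 7 of 14 rose and none fell (9 adjusted over the list alone). Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), the gene of the cyclin-dependent kinase inhibitor p21, rose 6.64-fold from 56.9 ± 28.4 to 378 ± 181 CPM, Ccng1, the cyclin G1 gene, 3.06-fold, and Bax, a pro-apoptotic gene, 3.38-fold. The median was 1.30 (camera adjusted p = 0.000108), and adjusted p = 0.232 with an estimated correlation. The level exceeded all controls in 6 of 6 embryos, the embryo labelled Klf5 siRNA 1 among them. The median was 0.80 without Klf5 siRNA 2 and 0.43 without embryos 2 and 4.

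Primitive endoderm genes had a median of −1.12 over 20 members (camera adjusted p = 0.00423), and adjusted p = 0.303 with an estimated correlation. Sox17 (ENSMUSG00000025902, chromosome 1, 4490931 to 4497354), an endoderm SRY-box factor gene, fell 11.3-fold from 17.2 ± 12.4 to 1.52 ± 1.37 CPM, Pdgfra, a growth factor receptor gene, 3.68-fold, and Lamc1, a basement membrane laminin gene, 2.86-fold. Cited1, a transcriptional coactivator gene, rose 14.7-fold, so that 3 fell and 1 rose (3 and 1 adjusted over the list alone), and 5 fell without Klf5 siRNA 5. The list level lay below all controls in 4 of 6 embryos. The list call was lost with the mitochondrial percent as a covariate, an alternative added after the data were seen (median −0.69, adjusted p = 0.113), as were those of Pdgfra (0.0999) and Lamc1 (0.0787). Cited1 lay at 3.06 rather than 3.88 on the log2 scale without Klf5 siRNA 5. The inner cell mass list did not pass (3 of 27 rose and 3 fell, the same numbers adjusted over the list alone; median −0.42, adjusted p = 0.579, and −0.17 and −0.18 without Klf5 siRNA 2 or 5). Within it Dppa3 rose 2.66-fold, Dppa4 2.05-fold and Klf2 2.30-fold, and Spp1, the osteopontin gene, fell 2.88-fold. Dppa4 was lost without Klf5 siRNA 4 (adjusted p = 0.0613) and with the mitochondrial covariate (log2 fold change 0.44, adjusted p = 0.333), Spp1 without embryos 2 and 4 (0.0555) and Klf2 without Klf5 siRNA 5 (adjusted p = 0.116). Pou5f1 lay at 2.17-fold (adjusted p = 0.0819) and Nanog at 1.85-fold (adjusted p = 0.0697).

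6 of 14 imprinted genes rose and none fell (7 adjusted over the list alone), among them Mest at 12.4-fold, Ascl2 at 7.64-fold and Phlda2 at 11.1-fold. The list level exceeded all controls in 5 of 6 embryos. The median was 1.59 (camera adjusted p = 0.0143), and adjusted p = 0.232 with an estimated correlation. The call was lost without Klf5 siRNA 2 (median 1.07, adjusted p = 0.0847), without embryos 2 and 4 (0.80, 0.127), with a filter at 5 CPM (0.126) and with voom quality weights (0.0685). 5 of 10 measured genes of the 2-cell-like state rose and none fell (5 adjusted over the list alone), with Arg2, an arginase gene, at 20.7-fold, Tmem92 at 5.72-fold, Sp110 at 3.60-fold and Gm4027, one of a multigene family and uncertain, at 25.5-fold. The rise was not shared by all embryos. The list level exceeded all controls (−0.53 to 0.48) in 4 of 6, lay within them in the embryo labelled Klf5 siRNA 1 (0.40) and below them in embryo 4 (−0.79). The median was 1.66 (camera adjusted p = 0.0277), and adjusted p = 0.303 with an estimated correlation. The list call was lost without Klf5 siRNA 3 (adjusted p = 0.0546) or 5 (adjusted p = 0.0782), 3 members rose without Klf5 siRNA 2, and the calls of Gm4027 without Klf5 siRNA 2 (log2 fold change 2.55, adjusted p = 0.211) and of Sp110 without Klf5 siRNA 3 (0.83, adjusted p = 0.157) were lost, as was that of Arg2 with limma voom (0.0685). The list call was also lost with the mitochondrial covariate (adjusted p = 0.103), the length offset (0.0808), limma voom (0.0532), a filter at 5 CPM (0.0695) and in the 12 embryos of the replicate block (0.0754 without the block and 0.130 with it). Integrated stress genes had 4 of 14 lower and none higher (5 and 1 adjusted over the list alone), with Nupr1 9.86-fold and Herpud1 3.83-fold lower, and a list level below all controls in 4 of 6 embryos. Nupr1 lay at −4.57 rather than −3.30 on the log2 scale without Klf5 siRNA 6, and Herpud1 lost its call with the number of detected genes as a covariate (adjusted p = 0.0607), with quality weights (0.0522) and with a replicate block (0.133). Their median was −0.80 (camera adjusted p = 0.0143), and adjusted p = 0.303 with an estimated correlation. The call was lost with a filter at 5 CPM (adjusted p = 0.0695) and without scramble embryos 5 and 6 (median −0.55, adjusted p = 0.0829), and the median was −1.49 with the mitochondrial covariate.

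The remaining lists did not pass in embryos. In the Krüppel-like family Klf2 rose and Klf5, Klf9 (1.64-fold lower) and Klf13 (1.97-fold lower) fell among 14 (1 and 3 adjusted over the list alone; median −0.52, adjusted p = 0.248). Glycolysis and hypoxia genes had 4 of 17 lower, with Vegfa 8.12-fold and Pgk1 1.96-fold, and 1 higher (6 and 2 adjusted over the list alone; median −0.65, adjusted p = 0.0526), and the list passed without any one of scramble embryos 1, 3, 4, 7 or 9 or Klf5 siRNA embryos 1, 4 or 5 (adjusted p = 0.0344 to 0.0461). Interferon-stimulated genes had Mx1 at 3.27-fold and Bst2 at 2.59-fold higher among 7 (2 adjusted over the list alone; median 0.57, adjusted p = 0.135, and 1.02 without scramble 6). Bst2 lost its call with the length offset (log2 fold change 0.57, adjusted p = 0.284) and with the mitochondrial covariate (1.10, 0.0819). In the YAP/TEAD list Ankrd1 rose 19.1-fold and Lats2 fell 3.85-fold among 10 (1 and 1 adjusted over the list alone; median −0.78, adjusted p = 0.287). Ier3 rose 15.4-fold among 14 FGF/ERK genes (1 adjusted over the list alone; median −0.94, adjusted p = 0.331), its log2 fold change of 3.94 being 4.53 without scramble 2 and 3.35 without Klf5 siRNA 5. Thy1 rose 19.1-fold as the 1 fibroblast marker measured (1 adjusted over the list alone; adjusted p = 0.209). Its log2 fold change of 4.25 was 3.16 without Klf5 siRNA 5, and its call was lost with the mitochondrial covariate (3.52, adjusted p = 0.0737). Dnmt3b, a DNA methyltransferase gene, fell 1.87-fold as the 1 of 9 formative genes that passed (0 adjusted over the list alone; median −0.48, adjusted p = 0.331). Dazl rose 7.69-fold among 12 germline genes (0 adjusted over the list alone; median 0.32, adjusted p = 0.996), and Zp3 11.9-fold among 6 maternal oocyte genes (0 adjusted over the list alone; median 0.59, adjusted p = 0.610). Cdx2 was the 1 of 8 WNT targets that fell, against a median of 0.43, a mean of 0.05 and a camera direction down (1 adjusted over the list alone; adjusted p = 0.744), and Eomes the 1 of 3 mesendoderm genes, against a median of 0.23 and a mean of −0.09 (1 adjusted over the list alone; adjusted p = 0.362). No gene passed among 17 lipid and cholesterol genes (0 adjusted over the list alone; Srebf2, log2 fold change −1.46, adjusted p = 0.0623; list median −0.63, adjusted p = 0.135), although both passed without Klf5 siRNA 3 (Srebf2 −2.43, adjusted p = 0.00256; list median −0.79, adjusted p = 0.0148). None passed among 2 neuroectoderm genes (0 adjusted over the list alone; Pax6, −0.41, adjusted p = 0.682; list median 0.10 against a camera direction down, adjusted p = 0.916). The same held for the Xist and Y-linked list, whose 4 measured genes did not include Xist (0 adjusted over the list alone). Uty stood at −0.67 (edgeR adjusted p = 0.621), and the list median was −0.34 (camera adjusted p = 0.798). Ankrd1 was lost without Klf5 siRNA 5 (log2 fold change 3.07, adjusted p = 0.114; 5.29 without scramble 10), and Lats2 without scramble 1 (0.0538), Klf5 siRNA 5 (0.0607) or 6 (0.0518). Dazl was lost without scramble 7 (0.0523), scramble 8 (0.0508), Klf5 siRNA 2 (0.114) or 4 (0.0817), and lay at 4.09 rather than 2.94 on the log2 scale without scramble 3. Klf9, Klf13, Dnmt3b and Zp3 lay next to the threshold (adjusted p = 0.0416, 0.0421, 0.0494 and 0.0492), and leaving out single embryos of either group took them as high as 0.0924, 0.0830, 0.0988 and 0.0769. All 4 were also lost with the mitochondrial covariate and with the length offset. In the 12 embryos of the replicate block Vegfa lost its call without the block (edgeR adjusted p = 0.0534) and with it (0.102). Pgk1 lost its call with the block (0.0588) and against a 1.5-fold change (0.120). The medians of the formative, interferon, germline, maternal oocyte, mesendoderm, neuroectoderm, lipid, and Xist and Y-linked lists moved by more than 1.5 times or changed sign with 1 embryo left out. Only those of the mesendoderm and neuroectoderm lists changed sign. No direction is read from any of these lists, since none passed camera with all embryos.

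Among single genes the smallest p values in embryos belonged to rising genes. Ypel5 rose 6.05-fold, Pemt, a phospholipid methyltransferase gene, 7.10-fold, and Cyb5a, the cytochrome b5 gene, 8.69-fold. Fth1, the ferritin heavy chain gene, rose 4.85-fold from 670 ± 231 to 3252 ± 734 CPM, Map1lc3b, encoding the autophagy protein LC3B, 4.51-fold from 3173 ± 1143 to 14311 ± 2732 CPM, and Sat1, encoding the polyamine acetyltransferase, 6.51-fold. Ppp1r14a rose 10.9-fold and Rpain 5.14-fold. Txnip (ENSMUSG00000038393, chromosome 3, 96557957 to 96561883), encoding a thioredoxin-binding regulator of glucose uptake, fell 24.5-fold from 46.0 ± 27.5 to 1.88 ± 1.23 CPM. Aldh18a1, a proline synthesis gene, fell 4.96-fold, Nxf7 7.26-fold, Ildr1 4.61-fold, Msn, the moesin gene, 3.61-fold, Brwd1 3.37-fold and Mpp7, a polarity scaffold gene, 3.01-fold. Each of the genes named in this paragraph moved in 6 of 6 embryos and its groups did not overlap. Of 12385 genes tested 2447 passed, 1489 higher and 958 lower, and 596 had groups that did not overlap, where chance gives 0.0250% of genes. Without the embryo labelled Klf5 siRNA 1, 2398 passed. With a test against a 1.5-fold change 947 passed. Of the 2447 genes only 1328 passed with the mitochondrial percent as a covariate and 1628 with the length offset, both alternatives chosen after the data were seen.

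**Figure D4:**
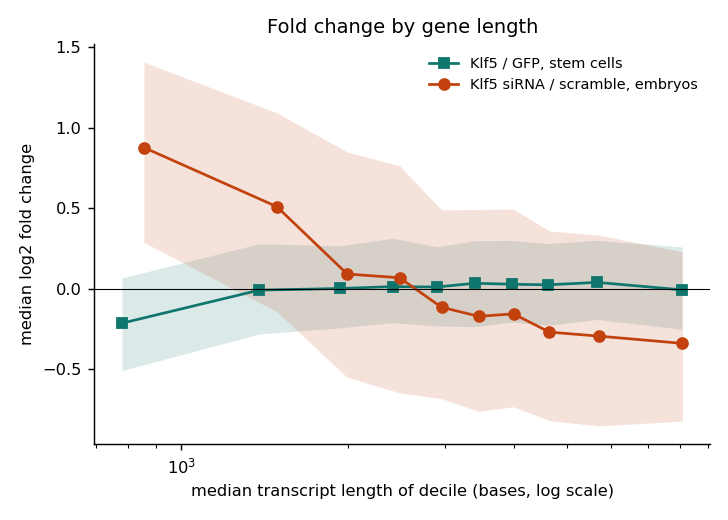
Median log2 fold change of genes in deciles of transcript length (horizontal log axis, bases), for Klf5 against GFP in ESCs and Klf5 siRNA against scramble siRNA in embryos; bands span the middle of each decile between its quartiles. In embryos the medians ran from 0.88 in the shortest decile to −0.34 in the longest, while in ESCs the Spearman correlation with length was 0.0959.

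The last comparison asks whether genes moved in opposite directions when Klf5 was raised in ESCs and lowered in embryos. The 2 experiments share no libraries. Of 62 genes other than Klf5 called in both, 42 moved in opposite directions and 20 in the same one. Of these 42, 30 rose and 12 fell in ESCs. Bmp4, a growth factor gene, rose 2.53-fold in ESCs and was at 0 in all 6 Klf5 siRNA embryos, at least 15.1-fold lower (3 counts per library as the floor). Slc9a3r1, a membrane scaffold gene, rose 2.08-fold and fell 3.65-fold, Ddah1 rose 1.93-fold and fell 3.36-fold, Zmiz1 rose 1.80-fold and fell 2.25-fold, and Dppa3 fell 4.02-fold and rose 2.66-fold. Nutf2-ps1 also went opposite ways and is uncertain. The embryo call of Zmiz1 was lost with the mitochondrial covariate (log2 fold change −0.52 rather than −1.17, adjusted p = 0.239), that of Nutf2-ps1 with the length offset (0.30, 0.286) and that of Bmp4 with quality weights (0.0596). Slc20a1, a phosphate transporter gene, was lower in both (1.78-fold and 2.63-fold), and Srxn1, Hal, Elobl, Cux2 and Sp110 were called higher in both. With the length offset Elobl did not differ in embryos by this test (log2 fold change 0.03 rather than 0.85, adjusted p = 0.947). Hal was lost there without embryos 2 and 4 (1.96 rather than 3.34, 0.0769), Sp110 without Klf5 siRNA 3 (0.83, 0.157), Srxn1 with a replicate block (0.0722) and Slc20a1 with the mitochondrial covariate (0.0621).

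Genes that rose with Klf5 in ESCs lay lower in Klf5 siRNA embryos. 142 of 204 had a negative fold change, with a median of −0.54 (camera adjusted p = 0.000114 over 4 sets), and adjusted p = 0.198 with an estimated correlation. Counting Klf5 itself, which both experiments set out to move, 31 genes that rose in ESCs fell in embryos, and 30 without it. Independent lists would share 16.4 (Fisher's exact p = 0.000609, adjusted 0.00244 over 4 pairs of directions). Another 14 rose in both where 24.7 would be shared (Fisher's exact adjusted p = 0.0343). Fisher's test takes genes as independent, which they are not, so its p-values do not measure the spread between embryos. Of genes that fell in ESCs, 12 rose in embryos where 15.9 would be shared (Fisher's exact adjusted p = 0.347), and 6 fell where 10.6 would be (adjusted 0.259). Genes that fell in ESCs had a median of −0.08 in embryos (camera adjusted p = 0.704). Genes that rose or fell in embryos had medians of −0.06 and 0.05 in ESCs (adjusted p = 0.166 for both). The Spearman correlation of fold changes across 11652 genes, which are not independent replicates, was −0.112 (Pearson −0.0731), and −0.0635 without Klf5 1 in ESCs.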

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

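8 of 190 groups of values held a sample far from the others by Dixon's test, where chance flags about 1 in 20 groups, so that about as many would be found by chance. No test in this part was chosen after the result was seen. Values are log2 CPM where no unit is given.

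Among the 10 scramble embryos, Cited1 was low in embryo 2 (−1.10, the nearest embryo at 2.33), Klf13 low in embryo 5 (3.55, nearest 4.46), Mest low in embryo 8 (−3.29, nearest 0.96) and Rpain high in embryo 9 (5.31, nearest 4.75).

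Among the 6 Klf5 siRNA embryos, Herpud1 was low in the embryo labelled Klf5 siRNA 1 (0.48, nearest 2.46) and Lats2 low in embryo 4 (−2.66, nearest 1.17). Embryo 2 had the highest mitochondrial share (10.3%, nearest 5.30%) and the lowest level of the maternal oocyte list (−1.39 relative to the control mean, nearest 0.58).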

How the results depend on the processing

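The alternatives chosen after the data were seen were the length offset, the sets without Klf5 siRNA embryos 2 and 4 or scramble embryos 5 and 6, the mitochondrial covariate, the crossed pairing, the Krüppel-like list without Klf5, DESeq2 on the genes that the edgeR filter keeps, the embryos of the replicate block without the block, and the comparison of both experiments without single libraries. No result past its threshold changed direction, except that the median of the Krüppel-like list in ESCs ran from −0.07 to 0.39 with its camera direction up throughout. Among results not past it, several list medians and the embryo values of Pax6 and Uty changed sign.

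The 444 genes called in ESCs became 1435 with DESeq2 and its own filter (1422 on the genes of the edgeR filter), 115 with limma voom, 870 with no filter, 1 against a 1.5-fold change, 155 with a replicate block and 1475 with a crossed pairing, and 1 to 998 with a library left out. Leaving out a library leaves 1 sample in a group, assumed to vary like the other. In embryos 1 of 6 pairs matched best with its own number. In ESCs the correlation between replicates of the same number was −0.108. With 2 libraries per group the crossed pairing must give the opposite sign, so this value cannot tell whether the numbers pair the ESC samples. Klf5 in ESCs stayed past the threshold in all 15 alternatives. In ESCs 11 lists passed camera, 10 with Klf5 left out of its list, 0 camera with an estimated correlation and 1 fry (neuroectoderm, which camera did not call).

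In embryos the 2447 genes became 947 against a 1.5-fold change. The replicate block leaves out scramble embryos 7 to 10, whose numbers have no partner. The other 12 embryos gave 1423 genes without the block and 902 with it. The mitochondrial covariate gave 2142, with only 1328 of the 2447 among them, and the length offset 2048, with 1628 of them. 7 lists passed camera, 4 with a filter at 5 CPM, 0 with an estimated correlation and 14 fry, which called all 7 and others. Klf5 kept its direction (−1.56 to −0.91 with an embryo left out) and missed the threshold against a 1.5-fold change (−1.07, adjusted p = 0.143), in those 12 embryos (−1.07, 0.0963, and −1.40, 0.0699 with the block), without the embryo with few detected genes (−0.91, 0.0583), without embryos 2 and 4 (−0.71, 0.131), with the mitochondrial covariate (−1.09, 0.0885) and with the length offset (−0.87, 0.0681). The genes rising in ESCs had medians of −0.67 to −0.39 in embryos over the refits and missed it only with an estimated correlation, which refits nothing (−0.54, adjusted p = 0.198). No embryo had a total low enough to be left out. Where samples were left out their smaller number is part of the change, and elsewhere the cause was not tested. Of 64 named genes called in embryos, 33 kept their call in all alternatives.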

Other observations

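Tests chosen only after the result was seen were those of the length offset on the trophectoderm and p53 lists, of fewer trophectoderm cells, of the feeder fibroblasts, and the levels of the other 4 embryos beside the set without embryos 2 and 4; the length offset, that set and the mitochondrial covariate were themselves added after the data were seen.

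Gene families found in the data rather than fixed beforehand also moved in Klf5 siRNA embryos. They were formed by symbol root alone, so a family can also hold genes of another function. Of 48 genes for large ribosomal subunit proteins (Rpl) 36 rose and 1 fell (median 1.10, camera adjusted p = 4.6e-18 over 195 families), and of 40 Rps genes 20 rose and 1 fell (0.90, 2.7e-08). Mitochondrial ribosomal genes rose in 31 of 48 (Mrpl, 0.98, 6.5e-18) and 18 of 29 (Mrps, 0.94, 6.2e-11), and proteasome genes in 7 of 9 (Psmb, 1.33, 1.9e-06). With an estimated correlation the adjusted p was 0.383, 0.547, 0.166, 0.166 and 0.166. Genes with the root Mcm, among them replication licensing genes, fell in 5 of 10 and rose in none (−0.89, camera adjusted p = 0.0149), and adjusted p = 0.383 with an estimated correlation. In ESCs 5 of 61 histone genes fell and none rose (Hist, −0.75, camera adjusted p = 4.8e-11 over 258 families). Of 16 Sox genes 3 rose (0.57, camera adjusted p = 3.1e-05). With an estimated correlation both families had an adjusted p of 0.985. The libraries hold polyadenylated RNA, and how evenly they capture histone transcripts was not tested.

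Y-linked transcripts exceeded 10 CPM in 6 of 10 scramble and 3 of 6 Klf5 siRNA embryos (Fisher's exact p = 1), with the lowest such embryo at 67.8 CPM and the highest other at 6.69 CPM. In ESCs they held 2.35 and 8.97 CPM in GFP cells and 8.86 and 0.827 CPM in Klf5 cells.

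Shorter genes lay higher and longer genes lower in Klf5 siRNA embryos. A length-dependent bias as the whole reason for the lower trophectoderm list is argued against. With a length offset its median was −1.26 (95% bootstrap interval −1.74 to −0.57, camera adjusted p = 1.8e-08). The same held for the higher p53 list, at 1.15 (0.69 to 1.95, camera adjusted p = 0.000229). Such a bias is not excluded, since the intervals cover genes and not embryos. The offset also removes only a smooth trend, whose median was −0.34 in the longest decile. Without the offset both lists missed the threshold by camera with an estimated correlation (adjusted p = 0.196 and 0.232). For 186 genes with the roots Rpl, Rps, Mrpl, Mrps, Psma and Psmb the offset took the median from 1.02 to 0.557 (0.487 to 0.671). With the offset 83 rose, so that length may account for part of their rise. Variation in mitochondrial share stays open too, the correlation of fold change with length being −0.110 with that share as a covariate, while an effect of the siRNA on RNA make-up was not tested.

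Trophectoderm genes lay lower in Klf5 siRNA embryos. A loss of trophectoderm cells alone would raise the markers of the other cell types alike. The primitive endoderm median of −1.12 (−1.56 to −0.51) argues against it, beside −0.42 (−0.81 to 0.48) for the inner cell mass list. Such a loss is not excluded, since the intervals cover genes and not embryos. The primitive endoderm list also lost its call with the mitochondrial covariate (−0.69, camera adjusted p = 0.113) and with an estimated correlation (camera adjusted p = 0.303). A joint loss of both cell types or a delay in development may remain and was not tested. Without embryos 2 and 4 the median was −0.846 (−1.34 to −0.42, camera adjusted p = 3.1e-05), an interval that reaches past the bound of −0.5 set beforehand. Since the interval crosses that bound, the test cannot tell whether embryos 2 and 4 are the whole reason. The other 4 embryos, a criterion added after this value was seen, lay at −1.67 to −0.53, all below the lowest control at −0.39. Every Klf5 siRNA embryo was already known to lie below all controls, so this outcome was fixed and is no separate test. It shows only that the lower level was not confined to embryos 2 and 4.

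Primitive endoderm genes lay higher in Klf5-overexpressing ESCs. More feeder fibroblasts as the whole reason are argued against, since the median of this list exceeded that of the fibroblast list by 1.11 (0.42 to 1.91). A part from feeders is not excluded. The interval covers the spread between genes and not between cultures, and 15 of 18 fibroblast markers had a positive fold change. Without Klf5 2 the primitive endoderm median was 0.77. Both Klf5 libraries lay above both GFP libraries, the lower by 0.720, which argues against a single library as the only carrier. It is no test of the groups, since with 2 against 2 libraries chance keeps groups apart in 33.3% of arrangements. An effect of Klf5 on primitive endoderm genes may be proposed as a hypothesis from these 4 libraries, while a difference between cultures that goes with the groups was not tested.

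Among 100 splits of the 16 embryos chance was an unlikely reason for the number of genes called (2447, highest other 1256), for the trophectoderm median (−1.20, highest other −0.766) and for the median of genes rising in ESCs (−0.54, highest other −0.377). For each, 1 split was as far from 0, the real one, and 1 in 100 is the smallest share these splits can give. They cannot separate the siRNA from anything else that goes with the groups, such as the order of library numbers. The split with 1256 genes set scramble embryos 5 and 6 with Klf5 siRNA embryos 3 to 6. Chance cannot be excluded for the number of lists past camera (7, highest other 8; 8 of 100 splits) or for the correlation between the experiments (−0.112, highest other −0.139; 8 of 100 splits).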
